A study of Homo sapiens with 2 samples.

How the data were processed

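Gene expression was measured in Huh7 cells, an established human hepatocellular carcinoma line, after lentiviral infection with either an empty vector or a vector carrying a short hairpin RNA against CD133 (shCD133). CD133 is the surface glycoprotein encoded by PROM1. Each condition was represented by 1 array, so the groups were vector (1 array) and shCD133 (1 array). Total RNA was isolated with TRIzol and amplified into biotin-labelled cRNA with an Illumina kit, per the labels' protocols. The cRNA was read on an Illumina bead array, on which each gene is represented by 1 or more oligonucleotide probes and the value of a probe is the brightness of its beads.

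The values analysed were the authors' processed values, deposited as log2 intensities. The log base is not given in the sources used here and was read as 2 from the range of the values, 6.65 to 15.6, which corresponds to unlogged intensities from 100.5 to 49870. GenomeStudio version 2011.1 is named in the submitters' processing notes, and its role is not given there. The sorted values of both arrays agreed to within 0.00044 at every rank, as they do after quantile normalization between arrays, and both medians were 8.66. Of 47323 probes in the deposited log2 table, 19665 (41.6%) had a value on both arrays and 27658 were null on both. The filter behind the null entries is not given in the sources used here. The lowest values near 100.5 show no sign of background subtraction, so fold changes of dim probes are compressed in these data. Quantile normalization forces both arrays to the same distribution. A change of most genes in 1 direction would therefore be spread over the others.

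A second deposited table holds non-normalized signals and detection p-values under 4 value columns whose names match neither sample's labels, and these columns were not used. The analysis planned before the data were examined had started from those signals, with background correction and detection p-values. It was replaced by the authors' log2 values. Consequently no detection call was available here, and each gene with a value on both arrays was treated as measured. Depth in the sense of counts does not apply to arrays, and precision is limited by their number.

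Probes were named from a platform annotation table dated 2016, with symbols checked by gene identifier against the RefSeq gene table of GRCh38.p14. Of the 19665 probes with a value, 15205 had 1 gene symbol, 2 had several and 4458 had none. For 15197 probes the gene identifier was found in the RefSeq table, and 8 kept the annotation's symbol. Only probes with 1 symbol were named. They represented 11579 genes, of which 2907 had more than 1 probe. A gene took the value of its probe with the highest mean over both arrays.

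The quantity compared was the log2 value of shCD133 minus that of vector. With 1 array per group there was no replicate error and no test, and no p-value is given. Genes were counted as different at a size of at least 2-fold (a log2 difference of 1). The named genes followed a rule fixed before the data were examined. It took PROM1, then the 12 genes with the largest difference in each direction whose probes all differed in the same direction, and within each gene list the 4 members with the largest absolute difference plus any member at least 2-fold different. A further part of the rule, for genes detected on 1 array only, could not be applied without detection calls. VEGFA, ADM, ATF4, ASNS, CEBPG, STAT3, SOCS3, EPCAM, AFP, GPC3, ALB, ACTB and MT2A are named outside this rule and were chosen after their values were seen, as were the genes named for families in the closing section. The only error that the data hold is the disagreement between probes of 1 gene. It covers measurement and differences between transcripts of a gene, and leaves out variation between cultures.

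Before the data were examined, 38 gene lists were fixed, covering stem cell markers, STAT3 targets, hypoxia, cell cycle, stress, metabolism, signalling, liver function and markers of other cell types. The median difference of each list was placed among the medians of 10000 random gene lists of the same size, matched on mean level in 20 bins. A list with at least 5 measured members was said to stand apart when its median lay outside the central 95% of the random medians. This describes these 2 arrays and does not test the conditions. Of the lists, 37 had enough members, and 1.85 of them would stand apart by chance if their members varied independently. Members of a list can vary together and lists share members, so chance alone could give more. Matching on gene length as well (10 bins of level by 5 of length) was added after the data had been seen. Gene length is the genomic span in the RefSeq table of GRCh38.p14 and was available for 11569 genes (99.9%).

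The alternatives were the mean over a gene's probes, a 1.5-fold threshold and unmatched random lists (planned), and 6 added after the data had been seen. These centred the differences on the median of all genes, removed the trend of the difference with mean level by lowess over a share of 0.4 of the genes, removed the trend with gene length in the same way, applied normexp background correction with an offset of 16 to the unlogged values, kept only genes with a mean of at least 8, and matched random lists on gene length. The procedure was tested on simulated data drawn from the real probe levels and the real disagreement between probes, with 200 of 11579 genes changed. It placed 94.0% of 100 genes changed by 1.5 on the log2 scale, and 100.0% of 100 genes changed by 3, past the 2-fold threshold in the right direction. In the same simulation 1.97% of unchanged genes passed it, and 5.0% of 200 unshifted lists of 20 genes stood apart. Of 50 lists shifted by 0.5, 100.0% stood apart. The simulated errors were drawn independently for each probe and without regard to level, and held no variation between cultures. The differences of all genes in the real data had an SD of 0.64. These rates therefore check the procedure and do not carry over to the 2 arrays. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and limma 3.58.1 in R 4.3.3.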

Results

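Huh7 hepatocellular carcinoma cells infected with an empty lentiviral vector were compared with Huh7 cells infected with a lentivirus expressing a short hairpin RNA against CD133 (shCD133). The series concerns the control of CD133, a surface glycoprotein used as a marker of liver cancer stem cells, by the transcription factor STAT3. Its arrays address which other transcripts differ when CD133 is reduced. There was 1 array per condition, so no value below has a replicate error, and all differences describe these 2 arrays. Values are the authors' quantile-normalized log2 intensities for 11579 named genes. Differences are shCD133 minus vector, also on the log2 scale. Differences of genes near the lowest value in the data on either array, where signal was not told from background, or near the highest are limited by the range of the scale. Over all probes with a value, the arrays correlated with a Pearson r of 0.948 (across probes, which are not independent replicates).

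PROM1, the gene that encodes CD133, was measured by 1 probe (ILMN_1786720, transcript NM_006017). Its log2 intensity was 13.58 with the vector and 10.83 with shCD133, a difference of -2.75, or 6.72-fold lower. The unlogged PROM1 intensity of the shCD133 array was 14.9% of that of the vector array. Across all named genes, 14 differed by more than PROM1 in the downward direction. Among the 231 genes of like mean level and like genomic length, PROM1 had the lowest difference, and the lowest of the others was -1.86. Their median was -0.04.

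More genes were lower with shCD133 than higher at the 2-fold threshold: 956 (8.26%) against 241 (2.08%). At 4-fold, 119 genes were lower and 12 were higher. The median gene was nevertheless slightly higher with shCD133, by 0.11, and 59.2% of genes lay above 0, so list medians below are to be read against 0.11. The share of higher genes among the 2-fold different ones was 20.1%. It was 12.3% after centring on the median gene, 9.59% after removing the trend with mean level and 32.3% after background correction, and 43.0% at a 1.5-fold threshold. The SD of the difference, estimated from 2907 genes with more than 1 probe, was 0.32 per probe. By the level of the dimmer of the 2 probes compared, it ranged from 0.39 at log2 levels under 8 to 0.13 at levels of 12 and above. Of 391 genes at least 2-fold different that had a second probe, 354 (90.5%) had a second probe with a difference in the same direction, and in 172 the second probe was also at least 2-fold different.

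**Figure D1:**
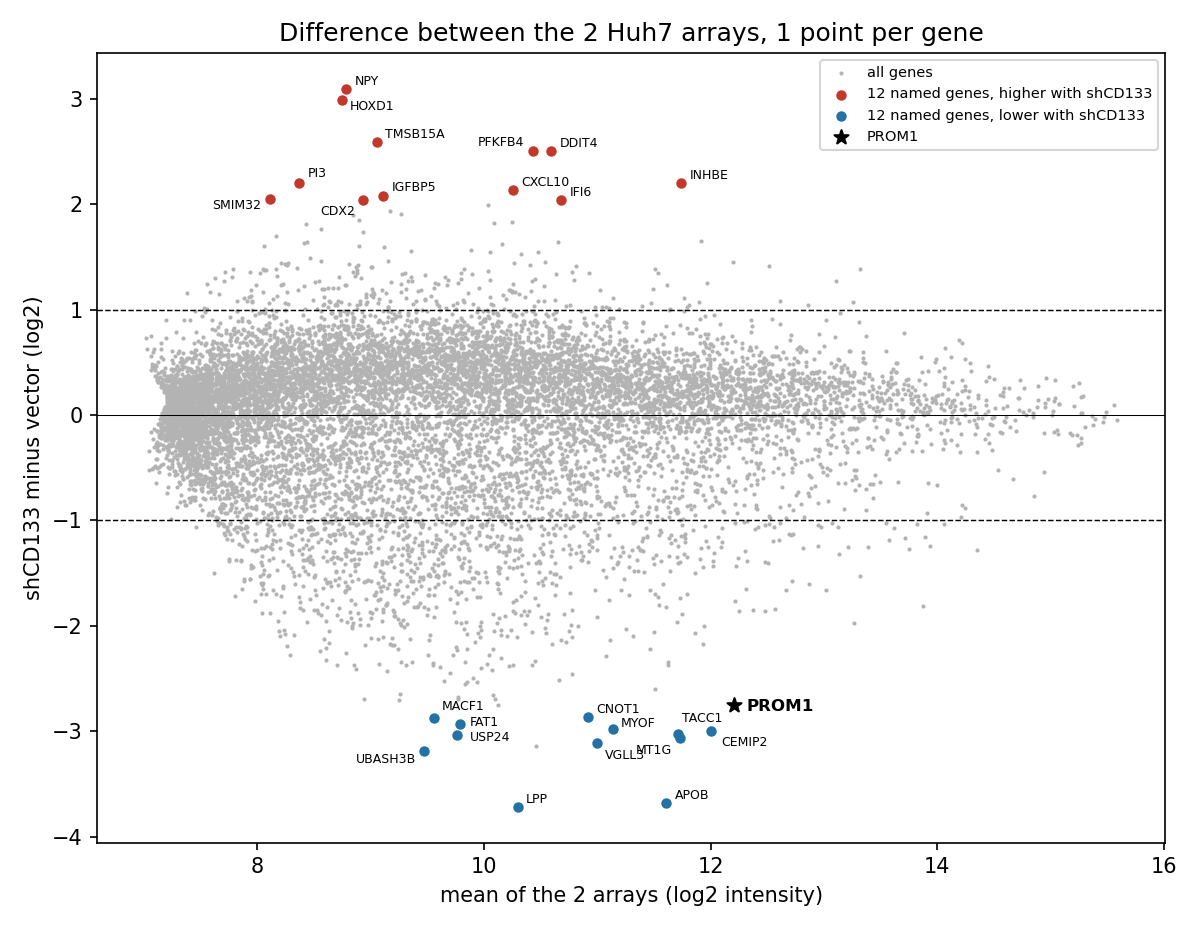
Difference between the arrays (shCD133 minus vector, log2) against the mean log2 intensity of both arrays, 1 point per gene, with the 2-fold lines dashed. PROM1 (star) lies at -2.75, the 12 named higher genes lie between 2.04 and 3.09, and the 12 named lower genes lie between -3.72 and -2.87.

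NPY, which encodes neuropeptide Y, was higher with shCD133 by 3.09, from 7.24 to 10.33. The homeobox gene HOXD1 was higher by 2.99 and the thymosin gene TMSB15A by 2.59. PFKFB4, a regulator of glycolytic flux, and DDIT4, a stress-induced inhibitor of mTOR signalling, were both higher by 2.51. The elastase inhibitor PI3 and the inhibin subunit gene INHBE both differed by 2.20. The interferon-induced chemokine CXCL10 was higher by 2.13, IGFBP5, an insulin-like growth factor binding protein, by 2.08, and SMIM32 by 2.05. CDX2, an intestinal homeobox factor, and the interferon-inducible IFI6 were each higher by 2.04. Several of these started near the lower end of the scale on the vector array, such as NPY (7.24), HOXD1 (7.25), PI3 (7.27) and SMIM32 (7.09), where differences are compressed and no fold is given. With background correction NPY differed by 4.60, HOXD1 by 4.46, SMIM32 by 3.77, PI3 by 3.53, TMSB15A by 3.39 and CDX2 by 2.67, and the order of the genes was another.

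LPP, a focal adhesion protein, differed by -3.72 on its brighter probe (13.1-fold lower with shCD133), from 12.16 to 8.44, and its other probe differed by -2.99. APOB, the structural protein of very-low-density lipoprotein, differed by -3.69 (12.9-fold lower), from 13.45 to 9.77. The phosphatase gene UBASH3B differed by -3.18, the transcriptional cofactor gene VGLL3 by -3.11 and the metallothionein MT1G by -3.06. USP24, a deubiquitinase, had a difference of -3.04 and TACC1 of -3.03, and CEMIP2, which encodes a cell-surface hyaluronidase, was 7.99-fold lower. The membrane-repair protein MYOF differed by -2.98, the giant cadherin FAT1 by -2.93, the cytoskeletal linker MACF1 by -2.88 and CNOT1, the scaffold of the CCR4-NOT deadenylase, by -2.87. The probes of UBASH3B (-3.18 and -0.62), MACF1 (-2.88 and -0.93) and CNOT1 (-2.87 and -0.92) agreed in direction but not in size. With the mean over probes these genes differed by -1.90, -1.90 and -1.89, and with background correction UBASH3B differed by -3.93 and MACF1 by -3.46. The rule passed over 1 lower gene whose probes differed in opposite directions.

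Genes lower with shCD133 tended to be longer. The median genomic length was 78.6 kb for genes at least 2-fold lower, 12 kb for genes at least 2-fold higher and 27.5 kb for all genes. Genes were split by length into 10 bins of like size. In the bin of the shortest genes 1.47% were at least 2-fold lower and 5.10% at least 2-fold higher, whereas in the bin of the longest 22.0% were lower and 0.605% higher. Across 11569 genes, which are not independent replicates, Spearman's rho between length and difference was -0.34. Within 10 bins of mean level rho lay between -0.45 and -0.23. Of the 12 named lower genes 11 were longer than the median gene (MT1G was not), and 11 of the 12 named higher genes were shorter.

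**Figure D2:**
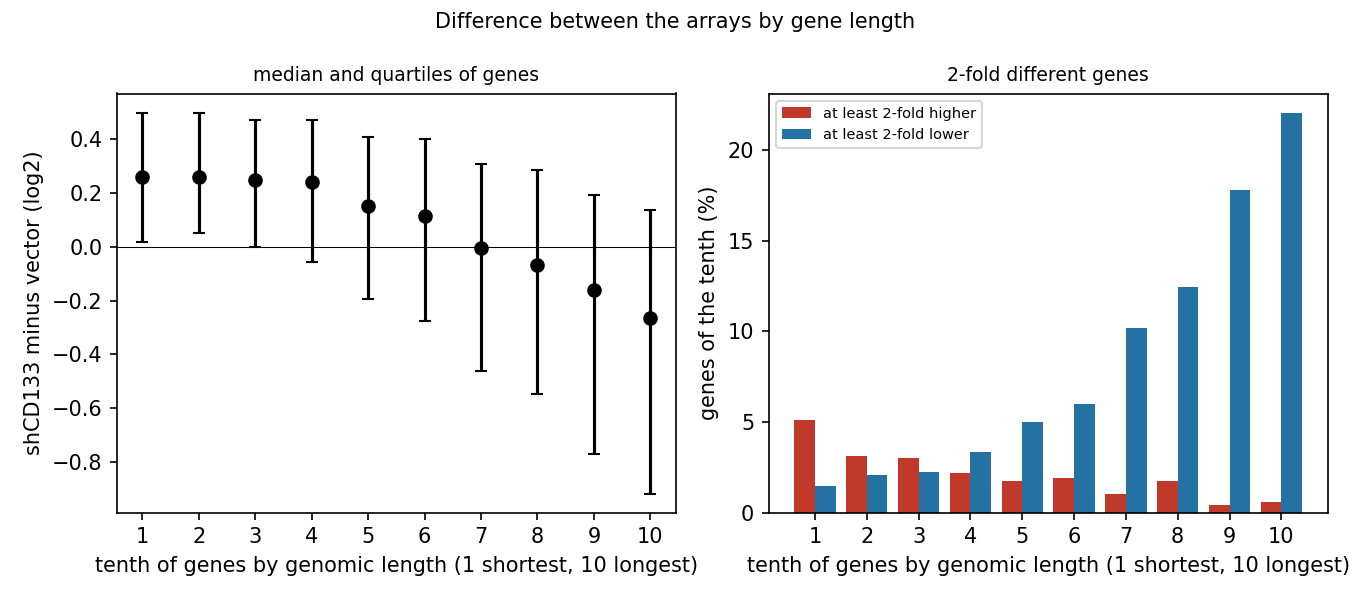
Genes in 10 bins by genomic length, from the shortest (1) to the longest (10). Left, the median difference (shCD133 minus vector, log2) with quartiles as bars, which goes from 0.26 in the bin of the shortest genes to -0.26 in the longest. Right, the percentage of genes at least 2-fold higher or lower, with 22.0% lower in the bin of the longest.

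Of 37 fixed gene lists with enough measured members, 13 had a median above the central 95% of random lists matched on level and 1 had a median below it. Lists of independently varying genes would give 1.85. Members of a list can vary together, so an excess over chance is not shown. With matching on gene length as well, 11 of the 14 lists stood apart on the same side. With that matching, acute-phase proteins, ER chaperones and ribosomal proteins also stood below, and fatty acid genes above.

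Hypoxia-inducible genes had a median of 0.64 over 25 measured members (random lists, -0.13 to 0.32). In this list 10 genes were at least 2-fold higher and none at least 2-fold lower. They were PFKFB4 (2.51), DDIT4 (2.51), the collagen cross-linking enzyme LOX (1.83), PFKFB3 (1.65), the glucose transporter SLC2A1 (1.45), NDRG1 (1.32), the mitophagy receptor BNIP3 (1.27), ALDOC (1.26), ANKRD37 (1.22) and PGK1 (1.05). VEGFA, the main angiogenic target of the pathway, differed by 0.62, and ADM by -0.32. The glycolysis list had a median of 0.41 over 19 members, 10 of which are also on the hypoxia list. Its remaining 9 members had a median of 0.33, and PFKL, the liver form of phosphofructokinase, was higher by 1.25. Both lists also stood above random lists matched on gene length.

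Amino acid response genes, the targets of ATF4, had a median of 0.60 over 23 members, of which 3 were at least 2-fold higher and 20 lay between the thresholds. The 3 were NUPR1 (1.43), STC2 (1.41) and the stress transcription factor ATF3 (1.13), followed by the cationic amino acid transporter SLC7A1 (0.96). ATF4 itself differed by 0.88 (its 3 probes ranged from 0.21 to 1.03), asparagine synthetase ASNS by 0.86 and CEBPG by -0.94. By contrast the unfolded protein response and ER chaperone list had a median of -0.14 over 19 members, inside the random range on level alone and below it with length matching, with the mean over probes (percentile 1.99) and with background correction (1.33). The list was inside the range with the length trend removed (median -0.09, percentile 8.13) and with the trend on mean level removed (percentile 8.9). At a mean level of 8 or more its median was 0.09 (percentile 40.3). CANX (calnexin, -1.40) and EDEM1 (-1.06) were at least 2-fold lower, followed by SEL1L (-0.98) and HSP90B1 (-0.90). Heat shock genes had a median of 0.11, with HSPD1 at -1.53, HSPH1 at -1.06, HSPA1A at 0.63 and BAG3 at -0.57.

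Interferon response genes had a median of 0.56 over 17 members, above the random range of -0.21 to 0.34, and remained above it with length matching. IFI6 (2.04) and the antiviral GTPase MX1 (1.29) were at least 2-fold higher, IRF1 differed by 0.84 and IRF9 by 0.74, and no member was at least 2-fold lower. Inflammatory cytokines and NF-kB targets had a median of 0.51 over 20 members, 4 of which were at least 2-fold higher: CXCL10 (2.13), the monocyte chemoattractant CCL2 (1.56), CXCL1 (1.33) and TNFAIP2 (1.03). In the RNA interference and double-stranded RNA sensing list the median was -0.21 over 13 members, inside the random range, and among members with a mean level of 8 or more it was -0.57, below the range (percentile 2.14). DICER1 (-1.48), the double-stranded RNA-activated kinase EIF2AK2 (-1.29) and AGO2 (-1.15) were at least 2-fold lower in that list, followed by DROSHA (-0.94).

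STAT3 target genes had a median of 0.32 over 23 members, just above the random range of -0.13 to 0.31 on level and inside it with length matching (percentile 91.6) and against unmatched lists (96.9). It was above the range with the length trend removed (median 0.34, percentile 98.5) and with background correction (0.61). CEBPD, an inflammatory transcription factor, was higher by 1.07 and the oncostatin M receptor OSMR was lower, with a difference of -1.36. The remaining 21 members lay between the thresholds, among them the feedback inhibitor SOCS1 (0.89), PIM2 (0.87), SOCS3 (0.32) and STAT3 itself (0.26). The other SOCS3 probe differed by -0.08, and SOCS3 was at 7.25 on the vector array, near the lower end of the scale. Acute-phase proteins, which STAT3 induces in hepatocytes, had a median of -0.10 over 17 members, inside the random range on level and below it with length matching or with the length trend removed. The iron hormone HAMP (1.81) and complement C3 (1.11, its other probe 0.58) were higher. The fibrinogen chain FGB (-1.32, its other probe -0.71) was lower, and SAA4 was at 0.98. SAA4 has close relatives, and its value is uncertain for that reason.

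Liver progenitor and cancer stem cell markers had a median of -0.14 over 16 members, inside the random range of -0.19 to 0.34 at percentile 4.41. With length matching the list was also inside, at percentile 2.74. PROM1 (-2.75), the hyaluronan receptor CD44 (-2.01) and CD47 (-1.12) were at least 2-fold lower and none was 2-fold higher. The hairpin targets PROM1, so its place here is no separate finding. SPP1 (osteopontin) differed by -0.79, EPCAM by -0.06, AFP by 0.14 at a level of 14.96 on the vector array, near the top of the scale, and GPC3 by -0.11. The 3 EPCAM probes ranged from -0.06 to 0.54. In the pluripotency and self-renewal list (median -0.03, 12 members) LIN28B, an RNA-binding pluripotency factor, was 4.01-fold lower and ZFX differed by -1.65, with SMO at 0.74 and BMI1 at -0.69.

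**Figure D3:**
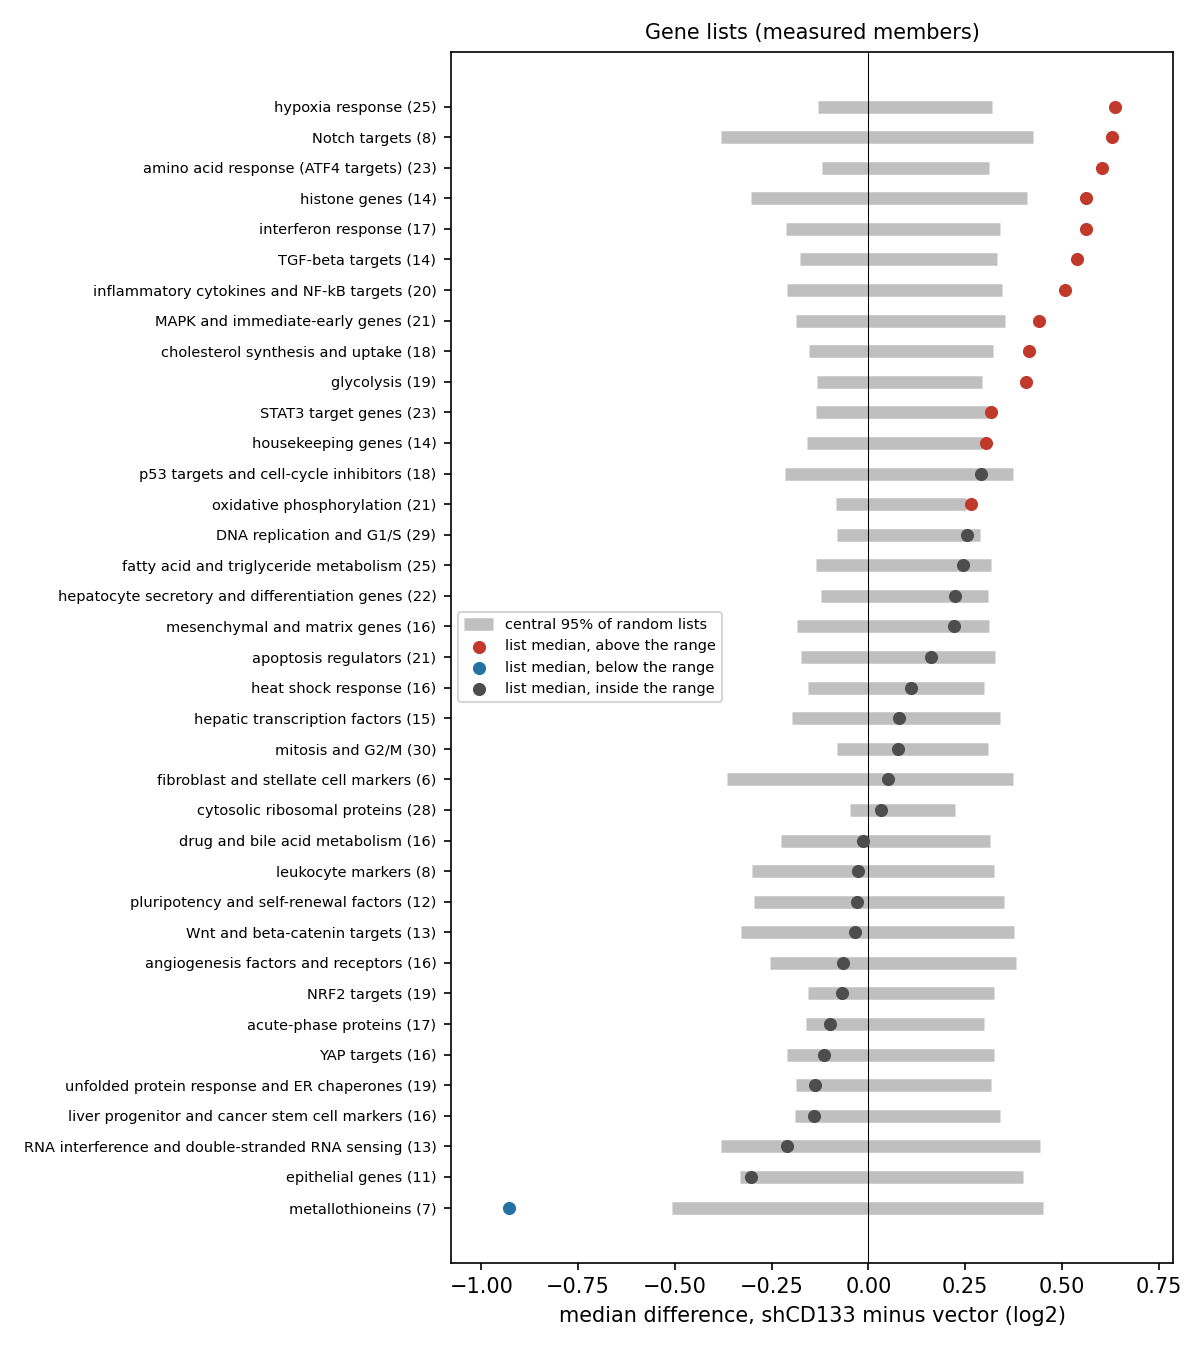
Median difference (shCD133 minus vector, log2) of each gene list with at least 5 measured members (number in parentheses), as points, over the central 95% of medians of random lists matched on level, as grey bars. Hypoxia response (0.64) and Notch targets (0.63) lie at the top of the plot and metallothioneins (-0.93) at the bottom.

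Metallothioneins, small zinc-binding proteins, were the list with the lowest median, -0.93 over 7 members (random lists, -0.51 to 0.45), and all 7 were below 0. MT1G (-3.06), MT1M (-1.49) and MT1H (-1.30) were at least 2-fold lower, and MT1F differed by -0.93 and MT2A by -0.68. The members are near-identical in sequence, so the value of a single member is uncertain. They are among the shorter genes, with a median length of 1.33 kb. Histone genes, with a median length of 0.63 kb, had a median of 0.56 over 14 members and none was 2-fold different. The highest were H2BC5 (0.88), H2AJ (0.83), H2AC20 (0.73) and H2AC18 (0.72), which also have near-identical relatives.

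Among signalling target lists, TGF-beta targets had a median of 0.54 over 14 members, with the inhibitors of differentiation ID3 (1.42), ID1 (1.39) and ID2 (1.00) higher and SMAD6 at 0.81. Notch targets had a median of 0.63 over 8 members, with NOTCH3 (1.60), HES6 (1.17) and HEYL (1.00) higher and HEY2 lower (-1.02). MAPK and immediate-early genes had a median of 0.44 over 21 members, with ATF3 at 1.13, JUNB at 0.80, SPRED1 at -1.52 and SPRED2 at -0.89. These 3 lists stood above random lists with and without length matching, but with the trend on gene length removed the MAPK list was inside the range, with a median of 0.27 (percentile 86.8). Wnt targets (median -0.03, 13 members) stood inside the random range, with SP5 (1.38) higher and CD44 (-2.01), TNFRSF19 (-1.51) and the secreted Wnt inhibitor DKK1 (-1.37) lower. YAP targets (median -0.11, 16 members) were also inside it, and below it with the trend on gene length removed (-0.21, percentile 1.69). There FJX1 was higher (1.90), and PTPN14 (-2.05), DLC1 (-1.77) and CRIM1 (-1.29) were lower, although the other PTPN14 probe differed by 0.12.

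The cell-cycle lists did not stand apart. DNA replication and G1/S genes had a median of 0.25 over 29 members, of which 3 were at least 2-fold lower: CDK6 (-2.55), the DNA polymerase subunit POLA1 (-1.87) and MCM10 (-1.41), with E2F2 at 0.82. Mitotic and G2/M genes had a median of 0.08 over 30 members. The proliferation marker MKI67 (-1.87) and the spindle motor KIF11 (-1.65) were lower there, with HMMR at 0.92 and TOP2A at -0.86. The p53 target and cell-cycle inhibitor list had a median of 0.29 over 18 members, with CDKN1A, which encodes p21, higher by 1.08 and CDKN2B (-1.41), ZMAT3 (-1.38) and TP53INP1 (-1.34) lower. In the apoptosis list (median 0.16, 21 members) only BIK (1.24) was 2-fold different, followed by CYCS (-0.87), BAD (0.77) and CASP9 (0.67).

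Liver functions showed single large differences without a shift of their lists. Hepatocyte secretory and differentiation genes had a median of 0.22 over 22 members. APOB (-3.69) and APOA2 (-1.81) were at least 2-fold lower, APOC3 (1.38) and the tryptophan-degrading enzyme TDO2 (1.25) were higher, and albumin (ALB) differed by -0.02 at a level of 15.48 on the vector array, near the top of the scale. Hepatic transcription factors had a median of 0.08 over 15 members, with PROX1 (-2.67), NR5A2 (-1.73) and ONECUT2 (-1.13) lower and ONECUT1 at -0.99. In the drug and bile acid list (median -0.01, 16 members) the canalicular exporter ABCC2 (-2.10), CYP1B1 (-1.83) and CYP4F3 (-1.08) were lower and CYP27A1 (1.01) was higher. NRF2 targets (median -0.07, 19 members) held AKR1C3 (1.99) and AKR1C2 (1.03), which are close relatives, on the higher side, and ABCC2 (-2.10) and TXNRD1 (-1.86) on the lower side.

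Cholesterol synthesis and uptake genes had a median of 0.42 over 18 members, above random lists with and without length matching. INSIG1, which restrains sterol synthesis, was higher by 1.03, followed by the enzymes MVK (0.91), FDPS (0.89) and TM7SF2 (0.87), and none was 2-fold lower. Fatty acid and triglyceride genes had a median of 0.25 over 25 members, inside the range on level and above it with length matching or with the length trend removed. ACSL5 (-1.55) was lower, with SREBF1 at 0.97, GPAM at -0.85 and ACACA at -0.83. Oxidative phosphorylation genes had a median of 0.27 over 21 members, above the range on level and inside it with length matching, with COX5B at 0.47, SDHA at 0.46, SDHC at 0.41 and NDUFA1 at 0.40.

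Epithelial genes had a median of -0.30 over 11 members, inside the random range of -0.33 to 0.40 at percentile 3.14. It stood below the range with the mean over probes (percentile 2.31), with the trend on mean level removed (2.40), with background correction (2.45) and at a mean level of 8 or more, where its median was -0.91 (0.18). It was inside the range with length matching (percentile 6.64) and with the length trend removed, where its median was -0.15 (8.31). The tight-junction scaffold TJP1 (-2.07), the desmosomal proteins DSP (-1.91) and PKP2 (-1.75) and the claudin CLDN1 (-1.16) were at least 2-fold lower. The members of this list had a median length of 45.0 kb. Mesenchymal and matrix genes had a median of 0.22 over 16 members, inside the range, and of 0.41 at a mean level of 8 or more, above it (percentile 98.2). None was 2-fold different, with CDH2 at -0.99, COL1A2 at 0.94, S100A4 at 0.87 and ITGA5 at 0.78. In the angiogenesis list (median -0.07, 16 members) THBS1 (-2.11), NRP1 (-1.89), ANGPT1 (-1.27) and FGF2 (-1.07) were lower. The other NRP1 probe differed by 0.48 and the other ANGPT1 probe by -0.67.

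Housekeeping genes had a median of 0.31 over 14 members, above the range on level and inside it with length matching. The transferrin receptor TFRC differed by -1.66, PGK1 by 1.05, PPIA by 0.85 and YWHAZ by -0.85, while ACTB differed by -0.01 at a level of 15.37 on the vector array, near the top of the scale. Cytosolic ribosomal protein genes had a median of 0.03 over 28 members, inside the range on level and below it with length matching, with RPS23 at -1.42, RPL7 at 0.72, RPL13 at 0.43 and RPL3 at 0.33 (its other probe, -0.29). Fibroblast and stellate cell markers had a median of 0.05 over 6 measured members of 14, with COL1A2 at 0.94, COL1A1 at 0.74, PDGFRA at -0.73 and DCN at 0.07. Leukocyte markers had a median of -0.03 over 8 members, with CD3D at -2.21, CD14 at 1.60, FCER1G at -0.50 and CD2 at 0.26. Only 2 endothelial markers of 14 had a value, LYVE1 (-1.09) and PECAM1 (-0.16).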

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

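The mean over a gene's probes, the 1.5-fold threshold and the unmatched random lists were planned, and the other alternatives were chosen after seeing the data. The planned changes of background correction, offset and detection filter were not run, because they need columns that could not be matched to a sample. Leaving out a replicate was impossible with 1 array per group. No paired analysis was possible because the groups share only 1 replicate number. PROM1 kept its direction under all alternatives, from -2.87 with the trend on mean level removed to -2.45 with the trend on gene length removed. It has 1 probe, so the mean over probes could not change its value. The counts of genes at least 2-fold higher and lower (241 and 956) became 1423 and 1883 at 1.5-fold and 734 and 1538 with normexp background correction, which widens the differences of dim genes. With the trend on mean level removed 134 genes were higher and 1263 lower, and lower genes outnumbered higher ones under all alternatives. The 24 named genes kept their direction in all 144 values. They had been chosen for large differences and for probes of the same direction, so this was largely fixed by the choice and shows no robustness. Of these values 22 moved by more than the SD per probe of 0.32, of which 12 did so with normexp background correction. The widest moves there were SMIM32 from 2.05 to 3.77, NPY from 3.09 to 4.60 and HOXD1 from 2.99 to 4.46, and with the mean over probes UBASH3B moved from -3.18 to -1.90, so the order of the named genes depends on these choices. Between 11 and 17 lists stood apart (the 17 among 35 lists left at a mean of 8 or more), against 14 in the main analysis. Of these 14, STAT3 targets, oxidative phosphorylation, housekeeping genes and MAPK genes each fell inside the random range under at least 1 alternative, with lowest percentiles of 91.6, 90.1, 90.4 and 86.8, the last of these with the trend on gene length removed. The other 10 of the 14 stood apart on the same side under the alternatives run. Centring on the median of all genes shifts lists and random lists alike, so it could not change the place of any list. Epithelial genes, ER chaperones, acute-phase proteins, fatty acid genes, ribosomal proteins, YAP targets, mesenchymal genes and the RNA interference list stood apart under at least 1 alternative and not in the main analysis. Hypoxia had the highest median in the main analysis (0.64), and at a mean level of 8 or more Notch targets had a higher one (0.87 against 0.75). With 1 array per group, variation between cultures is not measured.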

Other observations

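The gene family groupings, the scaling test of the hypoxia list and the cross-hybridization test of the metallothioneins were chosen after the results were seen. The other tests had their outcomes written down before they were run. Families sharing a symbol stem were compared with random lists matched on level. Of 76 families with at least 15 genes, 12 stood apart, 8 below and 4 above, where independently varying genes would give 3.8. Genes of a family can vary together, so chance alone could give more. With length matching 5 of the 12 still stood apart. The zinc finger genes (stem ZNF, 334 genes) had a median of -0.08, below all random lists at the given precision (percentile 0.00), with 24 at least 2-fold lower, such as ZNF106 (-2.49), a share below the 8.26% of all genes, and 5 higher, such as ZNF395 (1.44). RNA-binding motif genes (RBM, 32 genes) had a median of -0.13, with RBM47 lowest at -1.86. H/ACA small nucleolar RNA genes (SNORA, 44 genes) had a median of -0.11 and none was 2-fold different. Without detection calls, the signal of these SNORA probes was not told from background. Mediator subunits (MED, 24 genes) had a median of 0.39, although MED14 differed by -1.99, and the leucine-rich repeat family (LRRC, 28 genes) had a median of 0.32, with LRRC61 at 1.55. These 5 families stood apart with length matching as well. Nucleoporins (NUP, 22 genes, median -0.43, NUP153 at -2.31 and NUP205 at -2.29) and deubiquitinases (USP, 35 genes, median -0.30) stood below on level, and were inside the range with length matching, at percentiles 4.55 and 5.24.

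Genes lower with shCD133 tended to be long, and an effect of signal level or of the normalization is argued against, since the rank correlation of length and difference was below -0.05 in 10 of 10 bins of mean level. Genomic span alone was predicted to put genes with short transcripts in long genes below random lists. The 28 such genes (137.4 to 1504 kb), chosen from general knowledge of their transcripts, had a median of 0.30, at percentile 93.6 of random lists. None was 2-fold lower and 1 was 2-fold higher, while in the bin of the longest genes 22.0% of all genes were at least 2-fold lower. This argues against span alone for these 28 genes. A short list from general knowledge cannot decide it for the other long genes. Transcript length, through RNA integrity or labelling, was predicted to put genes with long transcripts in genes of 18.8 to 137.5 kb below random lists, but 20 such genes had a median of 0.30 (percentile 89.0), while 3 of them were at least 2-fold lower, against 12.4% of all genes of 54.3 to 84.8 kb, the bin that holds the list's median length. It stays open because the list rests on general knowledge of transcript lengths and left out 9 genes whose values had been seen. With these genes the median was 0.20 (percentile 67.4), but 7 of 29 were at least 2-fold lower and 1 was at least 2-fold higher. In the bin that holds the median length of these 29, 38.6 to 54.3 kb, 10.2% of all genes were at least 2-fold lower. Because values of the 9 genes had been seen, the count of 7 is no test. Base composition and untranslated regions, for which no sequence was used here, an off-target action of the hairpin and an effect of the loss of CD133 also stay open and untested.

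The hypoxia list had a higher median with shCD133, with 10 of 25 members at least 2-fold higher and 3 below 0. The trend with gene length is argued against as the cause, since the list's median was at percentile 100 of random lists matched on level and length. Scaling is argued against as the whole cause, since the median of all genes was 0.11 against 0.64 for the list. Once the trend on mean level was removed, the list's median was 0.52, at percentile 100 of random lists. That removal adds little, because the list was already at percentile 100 of random lists matched on mean level. A difference in cell density, oxygen or medium between the cultures may give such a pattern, and with 1 culture per condition it cannot be separated from an effect of the knockdown.

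All 7 measured metallothionein genes were below 0, 3 of them at least 2-fold lower with shCD133. The trend with gene length runs against this pattern, and after its removal the median stayed at percentile 0.03 of random lists. A single cross-hybridizing signal read to the same extent by all members is argued against by the range of their differences, 2.65 on the log2 scale. Because differences of dim probes are compressed, that range cannot decide on a shared signal read by probes of unlike brightness. Partial cross-hybridization, a difference in zinc supply between cultures and an effect of the knockdown stay open and were not tested.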
